A study of Mus musculus with 2 samples.

How the data were processed

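H3K79me2 ChIP-seq was done on bone-marrow-derived macrophages without stimulation in 2 biological replicates, which form 1 group. Per the labels, each library started from 10 ng of DNA, and the same control experiment is named for both. Per the deposited text notes, 4 peak lists on mm10 were made: a list of replicate 1 alone, a list of replicate 2 alone, a list from the pooled alignments, and a replicated list derived from the alignments of both replicates. The aligner, the peak caller, its thresholds and the rule behind the replicated list are not given in the sources used here. Depth per library is unknown, so no interval or floor that needs it is given.

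Each deposited list gives the start and end of every peak and 4 values made by the authors. The deposited score of a peak is a display value of at most 1000 and was not used. The fold of a peak over the control was computed by the authors, and the normalization behind it is not given in the sources used here; it served only to rank and filter peaks within a list. The deposited −log10 p and −log10 q of each peak are the authors' values. The q values were used only to count peaks with a q over 0.05, of which there were 5 in replicate 1's list, 9 in replicate 2's, 12 in the pooled list and 3 in the replicated list. Signal tracks and alignments were not used here.

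Peaks were merged within each list and set against the mouse genome GRCm38 with GENCODE M21, restricted to 21938 protein-coding genes on chromosomes 1 to 19, X and Y. A gene was called marked where at least 200 bp of the window from its outermost annotated 5′ end to 3 kb downstream, or to the gene's end if nearer, lay under the list. The replicated list was the main list. Peaks of the replicates were called shared at an overlap of 1 bp or more. The overlap of the replicates and the position of peaks along genes were tested against 1000 circular shifts of the intervals within each chromosome, one-sided, with a random seed of 20. For position, the smaller of the upper-tail and lower-tail p was taken, without correction for taking either side. The 5′ end of a gene was called CpG-rich where the 500 bp on both sides had an observed to expected CpG of at least 0.6 and a GC content of at least 50%.

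The share of marked genes in each of 32 lists was compared with that of all other coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 32 lists at 0.05. The lists, the tests, the marking rule and the alternatives were fixed before the data were examined, apart from the alternatives and tests named as later additions. The Hox, olfactory receptor, replication-dependent histone and keratin lists and the list of defensins and protamines were taken by a pattern of gene names, which also took Def6 and Def8, and the other lists by symbol or older symbol. Clec7a, Cxcl11 and Mx2 are not protein-coding in the annotation and were left out of their lists. Some genes stand in more than 1 list, such as Bst2 and Csf1r.

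The text names the 10 coding genes with the highest fold in their window, the 10 with the longest uninterrupted covered block, for each list up to 3 marked members with the most covered bases and up to 3 unmarked members in list order, every marked member where a list has 5 or fewer, the 5 longest covered genes marked in 1 replicate with no covered base in the other, and Spi1, Csf1r, Adgre1 and Dot1l. Some genes that this rule takes are not reported here. Genes that overlap another coding gene are named as such. Genes named outside this rule are said to have been chosen after their values were seen.

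In the comparison of the replicates within lists, each list with at least 10 genes marked in replicate 2 was compared with 10000 random draws of genes. The drawn genes were matched on replicate 2's fold and on gene length, each drawn from the 50 nearest neighbours. One-sided permutation tests were run in both directions for every list. Each direction was adjusted over 16 lists on its own, with no adjustment for testing both. The comparison was repeated with 1 member kept from each group of genes whose starts lay within 1 Mb, one with a base in replicate 1 where there was one. Sharing of X-linked and autosomal peaks was compared within 10 equal groups of replicate 2's ranking by fold, by a Mantel-Haenszel odds ratio.

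The code was tested on simulated data with known answers for 21938 genes. In the simulation of list marking, 5 of 5 lists made higher and 5 of 5 made lower were called, as was 1 of 22 unchanged lists. The planted differences were large and whether a gene was given a peak did not depend on its length. These calls therefore do not show that smaller differences would be found. Of 6339 genes given a peak, 100% were found marked, and 2.60% of the others were marked through an overlapping gene. The simulated Jaccard index was 0.497, equal to a count over single bases. In the simulated comparison of the replicates within lists, the 1 list with planted losses was called and 0 of 10 others were. Losses were planted gene by gene, without regard to neighbouring genes.

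The alternatives were each replicate's own list, the pooled list, peaks at or above the median fold of their list, minimum overlaps of 1 bp and 1000 bp, the whole gene body, a background of 10000 draws matched on gene length in 20 strata, merging across gaps of 1 kb, overlap of at least 50% of both peaks, and a stricter CpG definition (0.75 and 55%). Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.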

Results

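H3K79me2, a histone modification that the methyltransferase Dot1l places over the 5′ part of transcribed genes, was mapped by ChIP-seq in unstimulated bone-marrow-derived macrophages of C57BL/6J mice. The data form 1 group of 2 biological replicates, so the comparisons made were between the replicates, between genes and between regions of the genome. The labels give both replicates the same donor identifier, record the sex of neither, and do not say whether the cells came from separate animals or cultures. Replicate 1's list held 22979 peaks over 63.5 Mb and replicate 2's list held 31577 peaks over 114 Mb. The list that the authors made from both replicates, called the replicated list, held 15559 peaks over 93.2 Mb, which is 3.50% of the sequenced genome. Its median peak was 3483 bp wide and its widest was 123022 bp. The files give peaks and no read counts, so the depth of each library is unknown.

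The peaks in each replicate's list were called in that replicate alone. In the replicated list, 15202 of the 15559 peaks had the coordinates and fold of a peak called on the pooled reads. The fold of a peak over the control is the authors' value and was used only to rank peaks within a list. A gene is called marked where at least 200 bp of its first 3 kb, counted from the outermost annotated 5′ end, lay under the replicated list. An unmarked gene is one with no peak called there, which does not show that the modification was absent.

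H3K79me2 lay near the 5′ end of 6658 of 21938 protein-coding genes (30.3%), and 5962 genes were marked in both replicates' own lists. The highest fold, 38.0, was at Gnai2, which encodes an inhibitory G protein α subunit; peaks covered 17493 bp (82.3%) of this gene on chromosome 9 from 107614125 to 107635367 (mm10). Lamp1, which encodes a major lysosomal membrane protein and overlaps 1 other coding gene, followed at a fold of 37.6. Grb2, the adaptor that couples receptor tyrosine kinases to Ras, and the kinase gene Map3k1 were both at 37.2, with 62511 bp and 39219 bp covered. The stress-kinase target Mapkapk2 (36.8), the small GTPase gene Rap1b (36.4), the actin regulator Wasf2 (36.3), Vapb (36.0), Arhgap17 (35.8, overlapping 1 other coding gene) and the G protein gene Gna13 (35.7) completed the 10 highest.

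The longest uninterrupted block of H3K79me2 covered 123022 bp of Mbnl1, which encodes an RNA splicing factor, on chromosome 3. Blocks of 103543 bp in the receptor phosphatase gene Ptprj, 86338 bp in the actin-capping gene Capzb, 83572 bp in the transcription factor gene Foxo3 and 82783 bp in Trio followed. The kinase gene Gsk3b (82388 bp), Zfp516 (78506 bp), Fbxw11 (77862 bp), Med13l (75719 bp) and Tbl1xr1 (75133 bp) made up the rest of the 10 longest. Ptprj was unmarked at its outermost 5′ end and was marked at the 5′ end of another annotated transcript. Of the 15280 unmarked genes, 505 were marked at another transcript 5′ end in this way, and 14452 had no base under the replicated list.

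Genes that define macrophages carried the modification far more often than other genes. Of 24 macrophage transcription factor genes, 21 were marked, against 30.3% of other coding genes (two-sided Fisher's exact test, p = 9.50e-09, adjusted p = 3.38e-08 over 32 lists). Peaks covered 202317 bp (90.0%) of Runx1, a regulator of blood cell development, 120935 bp (90.4%) of Zeb2 and 114771 bp (81.0%) of Mef2a, which overlaps 1 other coding gene. Nr1h3, which encodes a liver X receptor, and Klf4 had no base under the replicated list, although Nr1h3 was marked in replicate 2 (1442 bp). Mef2c was unmarked at its outermost 5′ end, had 76741 bp covered further in and was marked at another transcript 5′ end. Of 20 macrophage identity genes, 14 were marked (exact p = 0.000297, adjusted p = 0.0005), with 51555 bp covered in Adgre1, the gene of the F4/80 antigen, and 22282 bp in the scavenger receptor gene Msr1. The scavenger receptor gene Marco had no covered base, and Cd163 was unmarked with 2545 bp covered.

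Spi1, the gene of the macrophage master regulator PU.1, had 27653 bp (82.9%) covered on chromosome 2 from 91082390 to 91115756. The highest fold in its first 3 kb, 18.8, belonged to a peak from 91084861 to 91091746. The 5′ end of its basic-set transcript lay further in, at 91096096, within the longest block of 19282 bp from 91095275 to 91114556. Csf1r, the receptor for the growth factor that macrophages depend on, was unmarked at its outermost annotated 5′ end at 61100598 on chromosome 18. Peaks nevertheless covered 18778 bp (59.5%) of Csf1r, which overlaps 1 other coding gene, and reached the 5′ ends of its basic-set transcripts at 61105572 and 61105852. Dot1l itself was marked, with 11422 bp (28.4%) covered at a fold of 21.7.

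**Figure D1:**
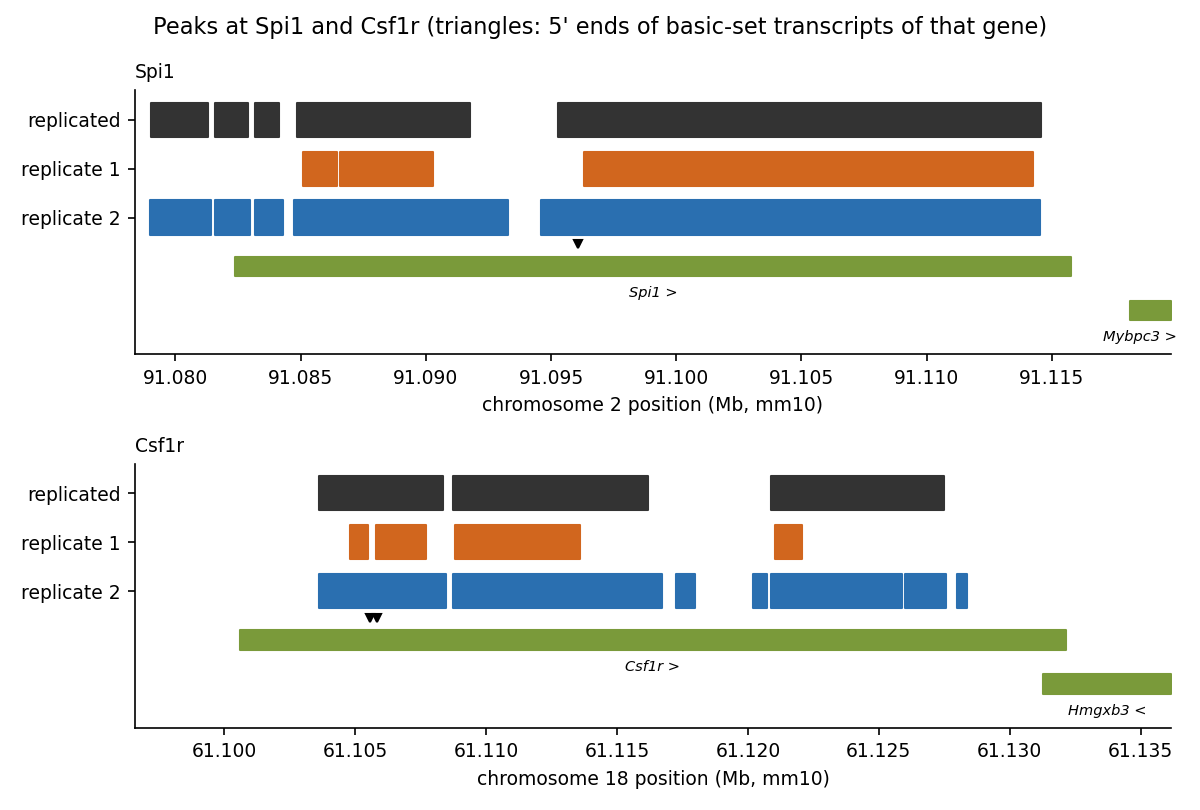
Peaks of the replicated list and of both replicates' own lists, drawn as blocks along chromosome position (Mb, mm10), at Spi1 and Csf1r, with genes in green, an arrowhead for each gene's strand and triangles at 5′ ends of basic-set transcripts. The replicated peaks covered 27653 bp of Spi1 and 18778 bp of Csf1r, and the Csf1r peaks began at 61103622, inside the annotated gene.

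Genes by which macrophages sense and signal the presence of microbes were marked in the resting cells. Of 22 pattern recognition receptor genes, 18 were marked (exact p = 8.90e-07, adjusted p = 2.19e-06), with 17944 bp covered in the inflammasome gene Nlrp3, 17710 bp in the endotoxin receptor gene Tlr4 and 16403 bp in the RNA sensor gene Tlr7. Tlr3, Tlr5 and Nod1 had no base under the replicated list, and Nod1 (24567 bp) and Tlr3 (628 bp) were marked in replicate 2. In NF-kB and Toll-like receptor signalling, 23 of 28 genes were marked (exact p = 2.13e-08, adjusted p = 6.80e-08), among them Traf3 (45565 bp, overlapping 1 other coding gene), Tab2 (44728 bp) and Irak2 (28355 bp). The NF-kB subunit genes Relb and Nfkb2, which overlaps 1 other coding gene, and the inhibitor gene Nfkbie had no base under the replicated list and were marked in replicate 2 (760 bp, 491 bp and 2520 bp). Of 24 cytokine and growth factor receptor genes, 17 were marked (exact p = 5.12e-05, adjusted p = 9.64e-05), with 41498 bp covered in Tgfbr2, 34286 bp in Tnfrsf11a, which encodes the receptor RANK, and 31677 bp in Tgfbr1. Csf2ra and Csf3r had no base under the replicated list, and Csf3r was marked in replicate 2 (3340 bp).

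Among genes that macrophages induce on stimulation, the share marked varied by class, though the classes were not tested against each other. Of 25 primary inflammatory response genes, 14 were marked (exact p = 0.00809, adjusted p = 0.0100), including Fos (3242 bp covered), Zfp36 (3175 bp), which encodes an mRNA-destabilising protein, and Btg2 (2966 bp), whereas the chemokine genes Cxcl1, Cxcl2 and Cxcl3 had no covered base. Of 17 secondary inflammatory response genes, 1 was marked (exact p = 0.0317, adjusted p = 0.0350): Il18 had 1014 bp covered, none of it in replicate 1's own list, and overlaps 2 other coding genes, while Il6, Il12a and Il12b had none. Of 31 interferon-stimulated genes, 20 were marked (exact p = 0.000102, adjusted p = 0.000181), with 30814 bp covered in Trim30a, 24348 bp in Parp14 and 17404 bp in Stat2, and none in Isg20 or in Irf7, which overlaps 1 other coding gene. Ifit2 was unmarked with 4824 bp covered, and marked in replicate 2. In replicate 2's own list 28 interferon-stimulated genes were marked, and 8 of these, Isg20 and Irf7 among them, had no covered base in replicate 1. The IL-4 alternative activation genes were marked in 4 of 17 cases (exact p = 0.792, adjusted p = 0.792): the marked ones were Pparg (18121 bp), Il4ra (15794 bp), Mrc1 (14213 bp) and Tfrc (3795 bp), and Arg1, Retnla and Chil3 had no covered base.

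Both inflammatory calls depended on the peak list and on other settings. The primary list was no longer past the threshold without replicate 2 (11 of 25 marked, exact adjusted p = 0.0789), with peaks at or above the median fold (6 of 25, adjusted p = 0.811) or with a minimum of 1000 bp (11 of 25, adjusted p = 0.127). The secondary list was not past it without replicate 1 (4 of 17, exact adjusted p = 0.448) or with the pooled list (4 of 17, adjusted p = 0.449). Its share of 1 of 17 was unchanged but not past it with a minimum of 1000 bp (exact adjusted p = 0.0633). Nor was it past it against the 24.9% of genes of matched length (permutation, adjusted p = 0.103).

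The machinery of uptake and degradation was widely marked. Of 31 lysosome genes, 27 were marked (exact p = 7.96e-11, adjusted p = 3.64e-10), with 39837 bp (95.8%) covered in the proton pump gene Atp6v0d1, 35452 bp in Scarb2 and 24220 bp in the protease gene Lgmn. Ctsk, which encodes the osteoclast protease cathepsin K, and Gaa had no covered base. Cd63 was unmarked at its outermost 5′ end with 2523 bp covered, and was marked at another transcript 5′ end. Of 29 genes of phagocytosis, Fc receptors and the oxidative burst, 22 were marked (exact p = 5.67e-07, adjusted p = 1.51e-06), with 135554 bp covered in the engulfment gene Elmo1, 107737 bp in Wdfy3 and 67473 bp in the Src-family kinase gene Lyn. Fcgr4 and Axl had none under the replicated list and were marked in replicate 2 (5462 bp and 3047 bp). Fcgr3 was unmarked at its outermost 5′ end with 7534 bp covered, and was marked at another transcript 5′ end. Antigen presentation genes were marked in 11 of 23 cases (exact p = 0.0732, adjusted p = 0.0756), with Nlrc5 (20776 bp), Canx (20611 bp) and Cd80 (13483 bp) marked and the MHC genes H2-K1, H2-Aa and H2-Ab1 without a base under the replicated list, though H2-K1 was marked in replicate 2 (2667 bp). That list passed the threshold without replicate 1 (17 of 23, exact adjusted p = 0.000373), with the pooled list (17 of 23, adjusted p = 0.00028) and with peaks at or above the median fold (10 of 23, adjusted p = 0.0260).

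The ribosomal protein, proteasome and cell cycle lists had the 3 highest shares of marked genes among the 32 lists. Of 77 ribosomal protein genes, 76 were marked (exact p = 1.76e-38, adjusted p = 2.82e-37). Peaks covered 9530 bp in Rps15a, 5813 bp in Rps3 and 5562 bp in Rpl5, which overlaps 1 other coding gene. Rps24 was unmarked at its outermost 5′ end, but had 4482 bp covered and was marked at another transcript 5′ end. Of 31 proteasome genes, 30 were marked (exact p = 6.10e-15, adjusted p = 4.88e-14). Peaks covered 45398 bp in Psmd14, 31474 bp in Psmb7, which overlaps 1 other coding gene, and 19249 bp in Psmb2. Psma6 was unmarked at its outermost 5′ end, but had 11061 bp covered and was marked at another transcript 5′ end. Cell cycle genes were marked in 29 of 32 cases (exact p = 1.62e-12, adjusted p = 8.89e-12), including the proliferation marker gene Mki67 (13683 bp), Cdk1 (12376 bp) and Cdk6 (127675 bp), while the cyclin genes Ccne1 and Ccnd2 had no covered base. Of 42 genes of H3K79 methylation and transcription elongation, 35 were marked (exact p = 1.67e-12, adjusted p = 8.89e-12), with 136581 bp in Aff1 and 44305 bp in the H3K36 methyltransferase gene Setd2; Mllt3 and Mllt6 had none under the replicated list, and Mllt6 was marked in replicate 2 (1523 bp).

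Genes of metabolism were also marked more often than other genes. Of 27 cholesterol and lipid handling genes, 21 were marked (exact p = 5.01e-07, adjusted p = 1.46e-06), with 35813 bp covered in the cholesterol exporter gene Abcg1, 31259 bp in Soat1, which esterifies cholesterol, and 23255 bp in the regulator gene Srebf2. Mvk had no covered base. Dhcr7 was unmarked at its outermost 5′ end with 1732 bp covered, and was marked at another transcript 5′ end. Of 19 glycolysis genes, 15 were marked (exact p = 1.73e-05, adjusted p = 3.45e-05), with 23719 bp in Pfkp, which overlaps 1 other coding gene, 22188 bp in Hk2 and 18888 bp in the glucose transporter gene Slc2a1. Aldoc had no covered base, and of the 2 annotated records of Aldoa, each overlapping 1 other coding gene, 1 was marked. Hk1 was unmarked at its outermost 5′ end with 27718 bp covered, and was marked at another transcript 5′ end.

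**Figure D2:**
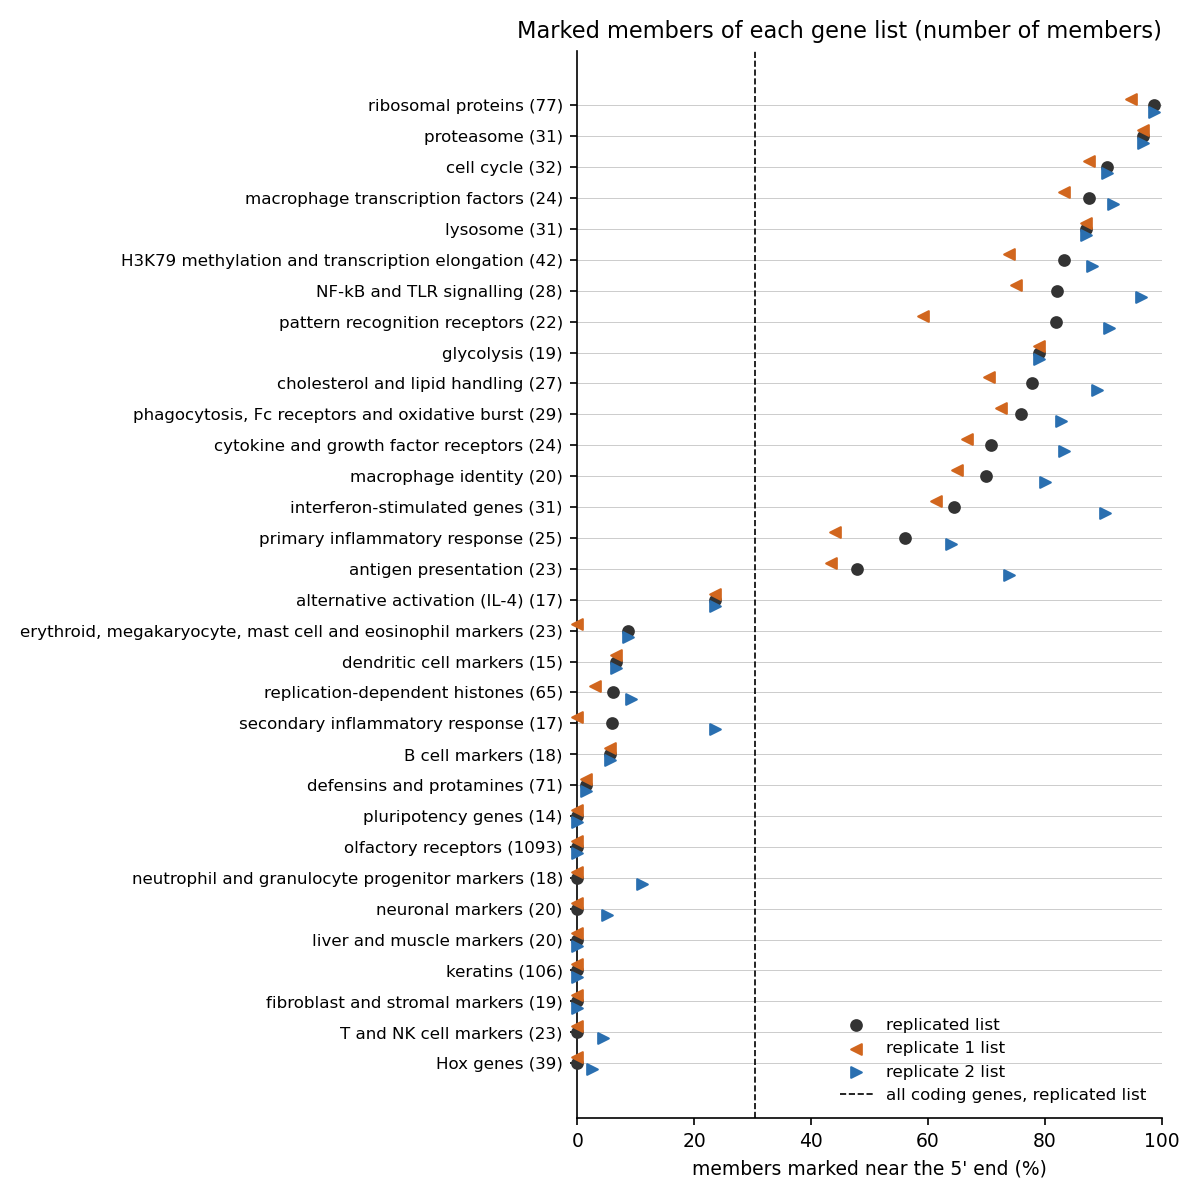
Percent of the members of each gene list that were marked near the 5′ end (x axis) in the replicated list (circles), replicate 1's list (left triangles) and replicate 2's list (right triangles), with the number of members in brackets and the share of all coding genes, 30.3%, as a dashed line. Ribosomal protein genes were at 98.7% in the replicated list and olfactory receptor genes at 0%.

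Markers of other lineages were rarely marked. None of 23 T and NK cell genes (exact p = 0.000364, adjusted p = 0.000582), 18 neutrophil and granulocyte progenitor genes (exact p = 0.00308, adjusted p = 0.0041), 19 fibroblast genes (exact p = 0.00173, adjusted p = 0.0024), 20 neuronal genes or 20 liver and muscle genes (exact p = 0.00102 and adjusted p = 0.00148 for each of these) was marked in the replicated list. Cd3d, Cd3e and Cd3g of the T cell receptor complex, the neutrophil genes Ly6g, S100a8 and S100a9, the collagen genes Col1a1, Col1a2 and Col3a1, and the albumin gene Alb had no covered base. Among 18 B cell genes, the adaptor gene Blnk was marked, with 26688 bp covered, and Cd79a and Cd79b had none (exact p = 0.0198, adjusted p = 0.0235). Among 23 erythroid, megakaryocyte, mast cell and eosinophil genes, Tal1 (2437 bp) and Pf4 (717 bp) were marked, both without a covered base in replicate 1, and Gata1, Klf1 and Epor had no covered base (exact p = 0.0224, adjusted p = 0.0256). Bst2, also an interferon-stimulated gene, was the 1 marked gene of 15 dendritic cell markers, with 2972 bp covered, and Flt3, Zbtb46 and Batf3 had none (exact p = 0.0496, adjusted p = 0.0529). The dendritic cell list passed the threshold without replicate 1 (exact adjusted p = 0.0295) and with the pooled list (adjusted p = 0.0296), and the B cell list did not with peaks at or above the median fold (adjusted p = 0.166) or among genes overlapping no other coding gene (adjusted p = 0.0918). The erythroid list was not past it against genes of matched length (permutation, adjusted p = 0.0533) or among non-overlapping genes (adjusted p = 0.0637).

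Olfactory receptor, keratin, Hox and pluripotency genes had no marked members in the replicated list. This held for 1093 olfactory receptor genes (exact p = 1.61e-177, adjusted p = 5.16e-176), 106 keratin genes (exact p = 3.10e-17, adjusted p = 3.31e-16), 39 Hox genes (exact p = 1.37e-06, adjusted p = 3.14e-06) and 14 pluripotency genes (exact p = 0.00814, adjusted p = 0.0100); Pou5f1, Nanog and Sox2 had no covered base. The pluripotency list was not past the threshold with peaks at or above the median fold (exact adjusted p = 0.0574). Of 71 genes taken by name as defensins and protamines, 1 was marked (exact p = 3.19e-10, adjusted p = 1.28e-09), and this was Def6, which encodes a guanine nucleotide exchange factor and no defensin. Of 65 replication-dependent histone genes, Hist1h2bc, Hist2h2be, Hist3h2a (overlapping 1 other coding gene) and Hist2h3c1 were marked (exact p = 2.41e-06, adjusted p = 5.14e-06), Hist1h2bc and Hist2h3c1 without a covered base in replicate 1. That share, 6.15%, was not past the threshold against the 8.06% of genes of matched length (permutation, adjusted p = 0.765). Of the 32 lists, 15 were marked more often and 14 less often than other genes at an adjusted p under 0.05. Genes are not replicates, so each list test describes this set of peaks.

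H3K79me2 peaks lay in gene bodies, mostly downstream of the annotated starts. Over all coding genes, 10.4% of the bases in the first 500 bp were covered, against 27.3% between 1500 and 2000 bp, where coverage was highest. Peaks covered 22.0% of the bases in the first 2 kb downstream of coding genes' 5′ ends, 5.79 times the mean of 3.79% over 1000 circular shifts of the peaks within chromosomes. The 2 kb upstream were covered at 5.84%, 1.54 times the shifted mean. Upstream coverage lay mostly where a neighbouring gene stood: it was 35.2% of upstream bases at the 2094 marked genes with another coding gene within 2 kb upstream and 3.19% at the 4564 without. Of all covered bases, 97.5% fell in coding gene bodies against 41.6% after shifting, with 89.5% in introns against 37.7% and 8.08% in exons against 3.92%. Each of these comparisons gave a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. The p is that of the side on which the value lay, without correction for taking either side.

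**Figure D3:**
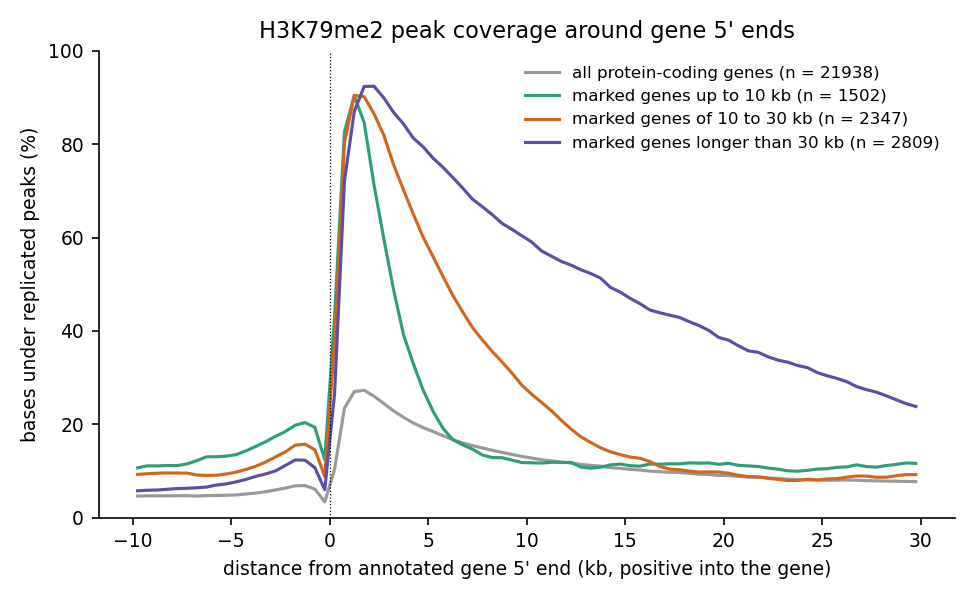
Percent of bases under replicated peaks (y axis) by distance from the annotated gene 5′ end (x axis, kb, positive into the gene), for all coding genes and for marked genes in 3 length classes. Marked genes were chosen for coverage in the first 3 kb, which raises their values there: in the 2809 longer than 30 kb, coverage peaked at 92.4% and was 59.0% at 10 kb and 38.0% at 20 kb, while in the 1502 marked genes of up to 10 kb it peaked at 90.4%.

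Longer genes carried longer stretches of the modification but a smaller covered share. Marked genes of up to 5 kb, 630 in number, had a median of 1968 bp (69.5% of the gene) covered, and the 644 marked genes over 100 kb had a median of 26411 bp (18.6%). Across the 6658 marked genes, covered length rose with gene length (Spearman's rho 0.645), and the covered share fell with it (rho -0.391). Both directions are partly built in, since covered length cannot exceed gene length and a marked gene has at least 200 bp covered. Genes are not independent replicates, and no p is given. The share of genes that were marked was 15.2% for genes of up to 5 kb, 41.9% for genes of 30 to 100 kb and 25.8% for longer ones.

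Genes with CpG-rich promoters were marked more often than others. Of 9737 genes with a CpG-rich 5′ end, 5265 (54.1%) were marked, and of the other 12201 genes 1393 (11.4%) were, an odds ratio of 9.13 (95% interval 8.52 to 9.79; the p of the two-sided Fisher's exact test was too small for the software to hold). Among chromosomes, peaks covered 6.25% of chromosome 11, the highest share, 5.27% of chromosome 19 and 1.10% of the X chromosome. On the X, 15.8% of the 948 coding genes were marked.

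The regions of H3K79me2 found in replicate 1 were nearly all found in replicate 2 as well, and replicate 2's list reached further. The lists shared 63.0 Mb, which is 99.2% of replicate 1's covered bases and 55.2% of replicate 2's. The Jaccard index of the covered bases was 0.550, 31.3 times the mean of 0.0175 over 1000 circular shifts (one-sided permutation p = 0.001, the smallest they can give). By peaks, 22677 of replicate 1's 22979 (98.7%) and 11547 of replicate 2's 31577 (36.6%) shared a base with the other list. Sharing followed height: ranked by fold in 4 equal groups, 96.8% of replicate 2's peaks in the highest group were shared and 2.61% in the lowest. Higher peaks were also wider, with a median of 6681.5 bp in the highest group and 603 bp in the lowest, and an overlap of 1 bp favours wide peaks. When at least 50% of each peak had to overlap, 25.7% of replicate 1's peaks and 18.7% of replicate 2's were shared, and 59.8% of replicate 2's highest group. Of the replicated list's peaks, 3796 (24.4%) had no base under replicate 1's own list, at a median percentile of fold of 15.9, and 538 had none under replicate 2's.

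**Figure D4:**
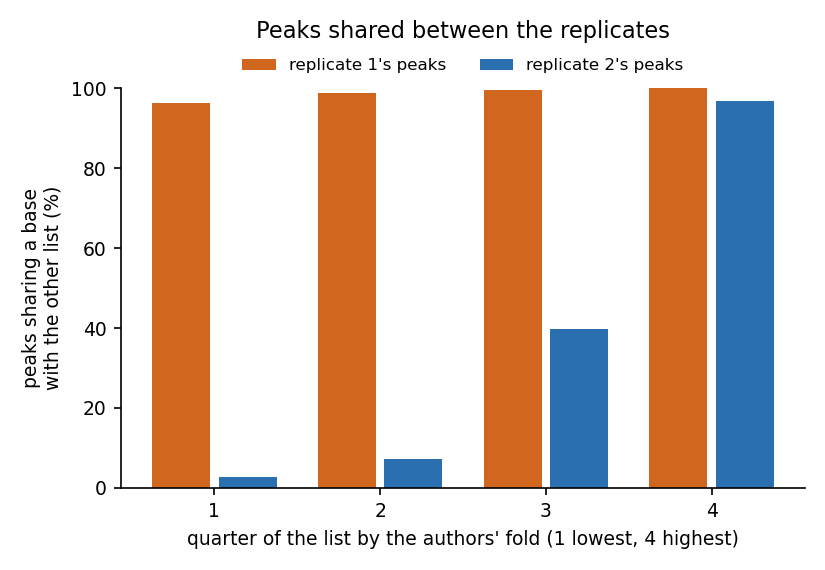
Percent of each replicate's peaks that shared at least 1 base with the other replicate's list (y axis), by group of the list when ranked on the authors' fold into 4 equal groups (x axis, 1 lowest, 4 highest). Replicate 1's peaks were shared at 96.3% or more in each group, and replicate 2's at 2.61%, 7.20%, 39.7% and 96.8%.

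Chromosome Y genes stood out among the genes marked in replicate 1 and free of peaks in replicate 2. There were 8 such genes, and the longest covered were Uty (16049 bp), Tanc1 (13177 bp), Ddx3y (7868 bp), Pcdh7 (4796 bp) and Eif2s3y (1647 bp); Uty, Ddx3y and Eif2s3y lie on the Y chromosome and are transcribed widely in male tissues. In the other direction, 1593 of the 7808 genes marked in replicate 2 (20.4%) had no covered base in replicate 1. The longest covered of these were Zfp704 (97310 bp), the phosphodiesterase gene Pde7b (83007 bp), the phosphatase gene Phlpp1 (63340 bp), the chromatin remodeller gene Chd7 (52757 bp) and Tbc1d8 (46544 bp, overlapping 1 other coding gene). With peaks at or above the median fold, the counts were 3 and 877, and with a minimum of 1000 bp 4 genes were in replicate 1 alone. There is 1 library on each side, so these differences were not tested.

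Xist, the non-coding RNA that silences an X chromosome in female cells, was chosen after its values were seen. Peaks covered 14685 bp of Xist in replicate 2 and none in replicate 1 or the replicated list, on chromosome X from 103460366 to 103483254, where the antisense gene Tsix and the coding gene Gm26992 overlap it. The X-linked relatives of the Y genes, Kdm6a, Ddx3x, Eif2s3x and Kdm5c, were covered in both replicates.

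**Figure D5:**
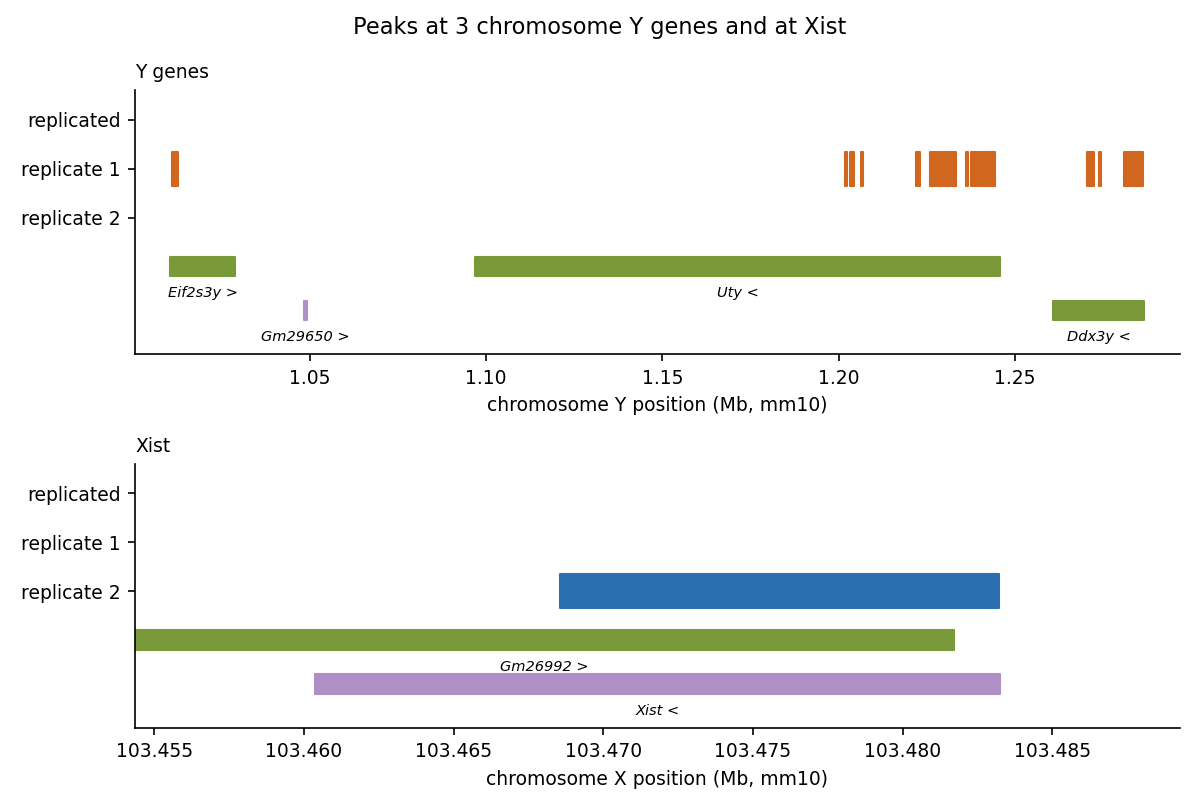
Peaks of the replicated list and of both replicates' own lists, drawn as blocks along chromosome position (Mb, mm10), at Eif2s3y, Uty and Ddx3y on chromosome Y and at Xist on chromosome X, with coding genes in green and non-coding genes in purple. The Y genes had 1647 bp, 16049 bp and 7868 bp covered in replicate 1 and none in replicate 2, and Xist had 14685 bp covered in replicate 2 alone of the 3 lists drawn.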

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

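Of the 69 values recomputed for the main results under an alternative, 58 were called the same and 11 moved. Among these 69 values, no test changed direction or side of the threshold. Tests of single lists entered them only as counts of lists past it, and 18 of 320 recomputed single-list tests did change side. A count was called the same within a fixed ratio of the main count, so 4884 marked genes against 6658 was the same. For chromosome shares and the correlation with gene length, the spread came from the single-replicate values being judged, which favours calling them the same. Marked genes numbered from 4884 with peaks at or above the median fold to 7808 in replicate 2's own list, and from 5975 to 7808 with a replicate left out. Lists past the threshold numbered 14 to 16 above and 11 to 14 below other genes over the alternatives run. Among the single lists, 302 of 320 recomputed tests kept their call, and among 174 named genes 77 of 1566 marking calls changed.

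How sharing was counted moved it most. With at least 50% of both peaks overlapping, 25.7% of replicate 1's peaks and 18.7% of replicate 2's were shared, and 63.8% and 59.8% of those in the highest of 4 groups by fold. With peaks at or above the median fold, the shares were 99.2% and 48.5%, and merging across 1 kb took replicate 2's share to 50.2%. Genes in replicate 2 alone numbered 877 and in replicate 1 alone 3 with peaks at or above the median fold, and 4 in replicate 1 alone with a minimum of 1000 bp. With a replicate left out, Spearman's rank correlation of covered length with gene length lay between 0.583 and 0.639. Under the stricter CpG definition, the odds ratio of marking was 6.31, with 3332 of the marked genes CpG-rich and 3326 not. The cause of these shifts was not tested.

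Chosen after seeing the data were marking at any transcript 5′ end (7163 genes marked), replicated peaks that share a base with both replicates' lists (6068), genes overlapping no other coding gene (4812), and the 50% overlap by fold group. No paired analysis was possible because there is 1 group. Depth is unknown, so a missing peak cannot be set against a limit of detection.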

Other observations

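The genes named in the first paragraph, the members named for the gene lists that differed between replicates, and the tests of those lists against genes matched on fold and length and with 1 member per group of neighbouring genes, the interferon-stimulated genes among them, were chosen only after the result was seen.

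Non-coding genes carried H3K79me2 too. Lncpint had 109888 bp (79.7%) under the replicated list, Gm14005 had 50524 bp, Pvt1 28902 bp, Lockd 19683 bp and Neat1, the RNA scaffold of paraspeckles, 18553 bp (89.3%). The host gene of the blood cell microRNA miR-142, Mir142hg, was covered over all of its 1694 bp in both replicates, while the host gene of the inflammatory microRNA miR-155, Mir155hg, and the imprinted genes H19 and Meg3 had no covered base. Of the replicated peaks, 575 (3.70%) had no base in a protein-coding gene, and 198 of these had none in any annotated gene.

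Gene lists differed in how many of the members marked in replicate 2 were free of peaks in replicate 1, a share of 20.4% over all genes marked in replicate 2. Of 28 interferon-stimulated genes marked in replicate 2, 8 (28.6%) had no covered base in replicate 1: Ifit3, Isg20, Irf7, Gbp2, Gbp3, Gbp7, Zbp1 and Ifi44. It was so for 6 of 20 pattern recognition receptor genes, among them Tlr2, Tlr9 and Nod1, against 10.4% of matched genes (one-sided permutation p = 0.001, adjusted p = 0.008 over 16 lists). In cytokine receptor genes the share was 20.0% (4 of 20), near that over all genes, against 7.53% of matched genes (permutation p = 0.0024, adjusted p = 0.0128). Fewer than in matched genes were found for ribosomal protein genes (1 of 76 against 14.4%) and cell cycle genes (1 of 29 against 22.6%; one-sided permutation, adjusted p = 0.0016 for each). Macrophage identity genes (0 of 16 against 13.9%, permutation p = 0.0306, adjusted p = 0.122) and primary inflammatory response genes (3 of 16 against 36.9%, permutation p = 0.0219, adjusted p = 0.117) leaned the same way without passing the adjusted threshold. Antigen presentation genes leaned to the higher side, at 6 of 17 (35.3%) against 18.7% (permutation p = 0.0229, adjusted p = 0.0916), also without passing it. Of the 16 lists, 3 passed on the higher side and 2 on the lower, and with 1 member per group of genes within 1 Mb none passed on the higher side (pattern recognition receptors, permutation, adjusted p = 0.106; cytokine receptors, 0.199). On the lower side ribosomal protein (permutation, adjusted p = 0.0016), cell cycle (0.0024) and primary inflammatory response genes (1 of 12 against 32.4%, 0.0325) then passed. Keeping a member with a base in replicate 1 favours the lower side and works against the higher one. The calls lost on the higher side may therefore come from that choice as well as from neighbouring genes. For primary inflammatory response genes, the lower call appeared only under that choice (permutation, adjusted p = 0.117 with all members). That call is therefore not taken as a result. These p-values compare 2 libraries, not conditions.

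For the interferon-stimulated genes, genes matched on replicate 2's fold and gene length lacked a peak in 8.68% of cases (one-sided permutation p = 0.000300, adjusted p = 0.0048). Matching also on covered length gave 10.0% (permutation p = 0.0001, the smallest that 10000 draws can give, adjusted p = 0.0008). The draws treat genes as independent, while Gbp2, Gbp3 and Gbp7 lie within 1 Mb of one another; with 1 member per such group, one with a base in replicate 1 where there was one, 4 of 19 (21.1%) lacked a peak, against 7.17% of genes matched on fold and length (permutation p = 0.0181, adjusted p = 0.145 over 16 lists) and 6.57% of those matched also on covered length (p = 0.0149, adjusted p = 0.119). The test of narrower marking was set beforehand at an unadjusted 0.05, which 0.0001 and 0.0149 pass, but that bar took members as independent and left out that the list was singled out among 16; after these values were seen, narrower marking was first read at that bar and then, like lower detection, at the adjusted one. The repeat with 1 member per group kept members by the outcome tested, which works against finding a higher share. Its count of 4 therefore reflects that choice as well as the neighbours. The first p-values treat neighbours as independent and the later ones rest on that choice, so neither decides. Lower detection in replicate 1 and narrower marking both stay open, and no biological explanation was tested, since the design has 1 group.

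Replicate 2's list covered 114 Mb and replicate 1's 63.5 Mb. Peaks found in replicate 2 alone lay low in its ranking, at a median percentile of fold of 31.9, as lower depth or enrichment in replicate 1 predicts. The 302 peaks found in replicate 1 alone also lay low in its own ranking, at 15.1. Low peaks are the ones most easily missed in either list, so this percentile cannot decide the cause. Depth and enrichment cannot be told apart here, and no biological explanation was tested.

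Chromosome Y held 19 peaks of replicate 1's list and 1 of replicate 2's, at 90723606 to 90724029 outside the 4 genes tested, and a peak over Xist stood in replicate 2's. In replicate 1, 3 of the 4 Y genes tested were marked (Uty, Ddx3y and Eif2s3y, not Kdm5d) and none in replicate 2, which is consistent with cells from mice of different sex, a hypothesis that the labels neither state nor rule out. The share of replicate 1's covered Y bases that lay in these 4 genes, 97.9%, argues against reads from repeats placed on the Y outside them. It cannot exclude misplaced reads from the X-linked relatives or from repeats inside these genes, which would fall in the same bases. Replicate 1 covered 46.2% as many bases of the X as replicate 2, against 51.0% to 59.6% of the autosomes. Pooled over like ranks of fold in replicate 2, X peaks were shared about as often as autosomal ones (odds ratio 1.00, 95% interval 0.792 to 1.26). Within single groups of rank the difference went both ways, with 3.85% of X peaks shared against 9.66% in group 5 and 89.8% against 82.0% in group 8. Lower ranking of X peaks may account for the ratio of covered bases. The test counted peaks that shared a base rather than covered bases, so it cannot decide this. A mixture of cells, a swapped sample and a Y-bearing contaminant were not told from a difference of sex by these tests.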
